A study of Oryza sativa with 6 samples.

How the data were processed

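Total RNA of seedlings, grown in artificial soil, was labelled with biotin and hybridised to Affymetrix rice genome arrays, 1 per biological replicate, 3 for the wild type and 3 for Epi-df, per the labels' protocols. The values analysed here are the probe set intensities the authors deposited, on a linear scale, made with MAS5 per the submitters' processing notes, with the version and the target of the scaling not given in the sources used here. The table holds 57381 probe sets, of which 123 are controls. No detection calls were used. Column medians of the non-control probe sets lay between 108.1 and 114.5 and differed by less than 0.1 on the log2 scale, so no further scaling was made. No 2 arrays held the same set of values.

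Groups and replicate numbers were taken from the sample titles. Values were tested as log2(intensity + 16) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided), without a replicate block. Probe sets whose mean over the 6 arrays lay under the 40th percentile were left out, which left 34355. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold, the thresholds the series' design names. Log2 changes are on the log2(intensity + 16) scale, which understates the change of dim probe sets, and ± after a log2 change is the standard error. Intensities are given as mean ± SD over 3 arrays. For statements per gene, the probe set with the highest mean stood for its gene except where stated. In 22 of 25 called genes with several tested probe sets, all of them went in 1 direction. The SWEET14 values are those of its probe set with the larger change.

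Probe sets were named through the platform annotation and a RefSeq gene table (assembly ASM3414082v1). Of the 57258 non-control probe sets, 22436 were paired with 1 gene, 95 with several and 34727 with none in this table, so the unpaired ones are unnamed here, not without a gene. The 17905 genes were all matched in the gene table, and 2457 of them had a name other than a locus number or clone. Of 86 genes fixed by symbol and locus before the data were examined, 58 had a named probe set.

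Gene lists were fixed before the data were examined, in part by patterns on description texts. The tables used here hold no description texts, so patterns on gene names took their place. They were written after the gene names were seen and before any change was computed. Lists of transposable elements and of receptor-like kinases could not be formed from names. Another 8 lists (DNA replication, phosphate starvation, iron and zinc transport, aquaporins, cellulose synthases, sugar transporters and invertases, dehydration and abscisic acid response, nitrogen) were added at that point. Lists with at least 5 tested genes were tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), and again with the correlation estimated from the residuals and with fry. None of the 3 lists that passed with the preset correlation passed with the estimated one or with fry.

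The text names, by a rule fixed before the data were examined, every measured Polycomb gene, the 10 largest rises and 10 largest falls among called probe sets with groups that did not overlap and an informative name (9 genes rose), and of each list up to 4 called members or, with none called, up to 2 with the highest mean, and any gene fixed by locus. An informative name took the place of the description text that the rule asked for. PBZ1, GA20OX3, GH3.1 and the probe sets and loci without a gene name were chosen after their values were seen.

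The fit was tested on simulated arrays of the same size with 200 changed probe sets: 98% of those changed by 1.5 and 99% of those changed by 2.5 on the log2 scale were called in the right direction, with 0 calls among the unchanged ones. These simulated arrays have independent genes and no differences between samples beyond each probe set's own spread. No change smaller than 1.5 was simulated, while the called probe sets had a median absolute log2 change of 1.325. The shares above therefore do not say how many smaller or more variable changes are found in the real arrays. Alternatives were another pseudocount, other filters, quantile or median scaling, other spread models, array weights, a replicate block, leaving out each array, leaving out probe sets with the suffixes _s_at and _x_at, other fold thresholds and Storey's q.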

Results

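RNA from rice seedlings of the japonica type, 3 weeks old, was measured on 6 Affymetrix rice genome arrays. They hold 3 biological replicates of the wild type and 3 of Epi-df. Epi-df is known as a dwarf line that carries an epigenetic allele of FIE1, a gene of the Polycomb group, whose complexes place repressive marks on histones. The arrays were alike in level: their median intensity lay between 108.1 and 114.5. Pearson correlations over all non-control probe sets were 0.989 to 0.994 within groups and 0.982 to 0.992 between them, and these correlations run across probe sets, which are not independent replicates. The ratio of the 3' to the 5' actin probe set, often read as a sign of RNA quality, was 9.83 to 10.7 in the wild type arrays and 7.73 to 13.8 in the Epi-df arrays. For GAPDH the ratio was 1.96 to 2.33 and 1.63 to 2.11. For the dap spike, which is not sample RNA, it was 4.01 to 4.695 and 3.20 to 6.135. The actin and spike ratios were both highest in Epi-df replicate 1 and lowest in Epi-df replicate 2, so the actin ratio may not reflect sample RNA alone. The number of arrays limits the precision of every value.

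The comparison of Epi-df with wild type asked which transcripts differ between the lines in seedlings. The gene for a gibberellin 20-oxidase, GA20OX2 (SD1, the semi-dwarf gene), fell in Epi-df from an intensity of 960.2 ± 352 to 174.5 ± 23.4 (mean ± SD, n = 3 in each group). The auxin transporter gene PIN5A fell from 1220 ± 22.2 to 280.1 ± 31.9. Among MADS-box genes, the flowering regulators MADS50 and MADS55 fell, while MADS16, a floral organ identity gene, rose from 632 ± 15.9 to 1616 ± 197. In all, 209 of 34355 tested probe sets changed by at least 2-fold at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg), 60 of them higher and 149 lower in Epi-df. The count was 108 without wild type replicate 1 (38 higher and 70 lower) and 114 without wild type replicate 2 (40 higher and 74 lower). Without Epi-df replicate 2 it was 216, 89 higher and 127 lower.

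**Figure D1:**
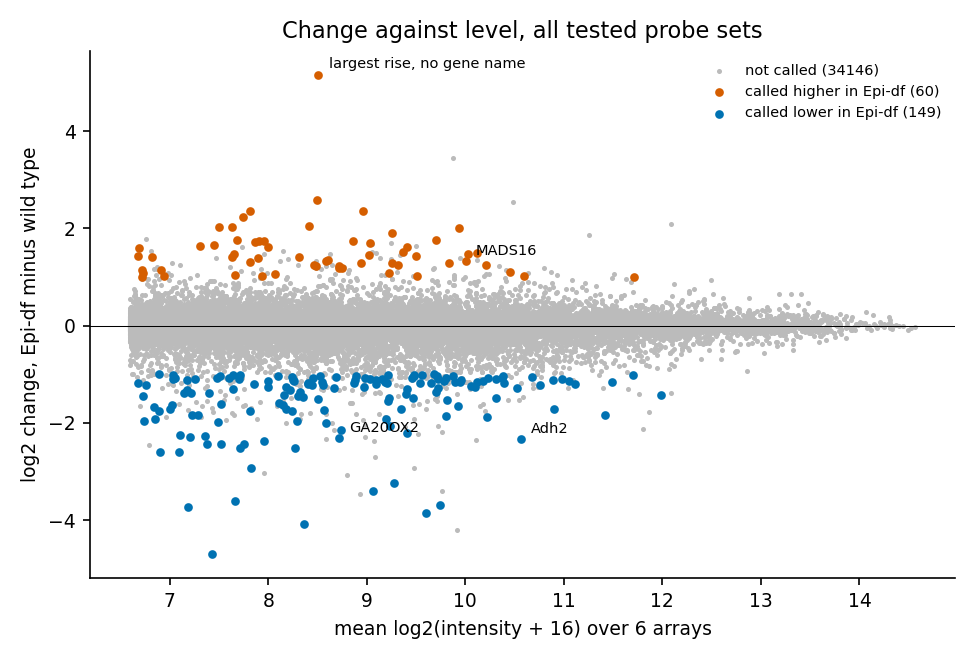
Log2 change, Epi-df minus wild type, against the mean log2(intensity + 16) over 6 arrays, for each of 34355 tested probe sets. The 60 probe sets called higher are orange and the 149 called lower are blue, and the largest rise, of a probe set without a gene name, stands at 5.16.

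The 143 called probe sets that the annotation pairs with 1 gene stand for 131 genes, 41 higher and 90 lower, and 28 of these genes carry a name beyond a locus number. The other 66 called probe sets had no single gene in the table used. The largest rise was that of a probe set without a gene name, from 44.9 ± 3.03 to 2167 ± 236 (log2 change 5.16 ± 0.10 SE, limma adjusted p = 3.06e-06). The tables used here do not say which gene it measures, so whether it measures FIE1 is open. Steep falls were seen in genes known only by locus: LOC4350599 went from 875.4 ± 192 to 18.9 ± 9.55, and LOC4331452 from 605.1 ± 11.1 to 66.4 ± 2.76. More than 4-fold changes were called for 9 probe sets that rose and 26 that fell.

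Genes of the Polycomb list were measured first. The tables used here name neither FIE1 nor FIE2, but they hold a gene named fie, without saying which of the FIE genes it is. Its intensity was 1877 ± 157 in wild type and 1948 ± 79.9 in Epi-df (log2 change 0.06 ± 0.09 SE, limma adjusted p = 0.855). EZ1, a histone methyltransferase of the same complex, was at 716.1 ± 10.3 and 706.3 ± 37.5 (limma adjusted p = 0.948). The values of fie and EZ1 therefore do not check the labels of the Epi-df arrays, and whether any other probe set measures FIE1 was not settled here. Of the 4 tested genes for DNA methylation none was called. The maintenance methyltransferase gene MET1-2 had a log2 change of 0.35 ± 0.20, CMT3A one of 0.22 ± 0.23 and DRM2 one of 0.06 ± 0.09. Without Epi-df replicate 3, where MET1-2 and CMT3A were lower than in the other Epi-df arrays, their changes were 0.60 and 0.51 (limma adjusted p = 0.0571 and 0.0799). CMT3A was at 0.09 without Epi-df replicate 1 and 0.07 without Epi-df replicate 2, and MET1-2 at 0.22 and 0.24.

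Among 12 tested MADS-box genes, 4 were called both over all probe sets and adjusted over the list alone. MADS50, an activator of flowering related to SOC1, fell by 1.31 ± 0.10 on the log2 scale (limma adjusted p = 0.00182). MADS55, of the group of SVP, fell by 1.45 ± 0.16. MADS16, the class B gene of petal-like organs and stamens, rose by 1.33 ± 0.10 (limma adjusted p = 0.00204). MADS27, of a family known from roots and nitrate responses, rose by 1.15 ± 0.14 from a low level of 54.9 ± 7.1 to 142.7 ± 31.2. The call of MADS27 was lost without wild type replicate 1 or 2 (highest limma adjusted p 0.0712). Without Epi-df replicate 3 it was not among the tested probe sets. As a whole the list did not pass the test, with 8 members higher and 4 lower and a median log2 change of 0.09 (camera adjusted p = 0.268, and adjusted p = 0.626 with an estimated correlation). Without wild type replicate 1 it passed, with a median of 0.28 (camera adjusted p = 0.0306), and without Epi-df replicate 3 its median was 0.0009 (camera adjusted p = 0.759). The 7 tested flowering time and clock genes had no call (camera adjusted p = 0.519). GI and PRR73, components of the circadian clock, differed between the groups by -0.04 ± 0.06 and -0.01 ± 0.07, and the flowering regulator HD1 by -0.47 ± 0.13 (limma adjusted p = 0.138).

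**Figure D2:**
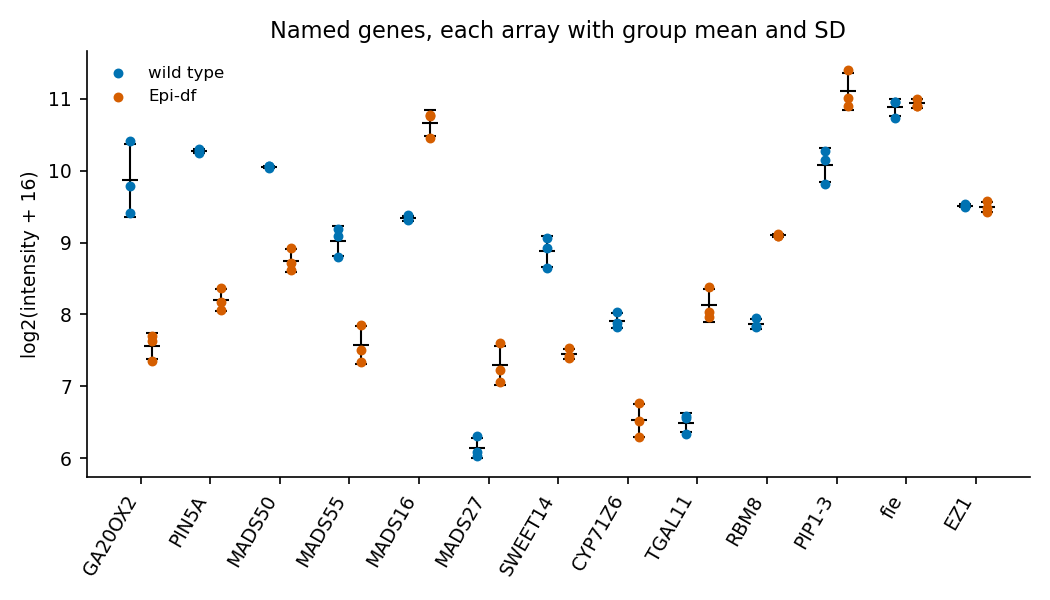
Log2(intensity + 16) of 13 named genes in each of 6 arrays. Points are single arrays, bars are the mean and SD of 3 arrays, wild type blue and Epi-df orange. The groups do not overlap for the first 11 genes and do for fie and EZ1.

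Among 9 tested gibberellin genes, GA20OX2 was the 1 called, over all probe sets and adjusted over the list alone. It fell by 2.30 ± 0.24 (limma adjusted p = 0.00594), and the call held without any single array. KAO, CPS1 and KO2, which act earlier in gibberellin synthesis, had log2 changes of -0.85 ± 0.21, -0.53 ± 0.22 and -0.44 ± 0.12 that did not pass the test. KAO and CPS1 were lowest in Epi-df replicate 3, and without this array their changes were -0.59 and -0.27 (limma adjusted p = 0.0736 and 0.387). KS1, of the same early steps, was at -0.11 ± 0.10, and GA20OX3, another 20-oxidase gene, at 0.35 ± 0.20, with 0.21 without Epi-df replicate 3 and 0.57 without Epi-df replicate 2. The DELLA repressor gene SLR1 and the receptor gene GID1 had changes of 0.09 ± 0.09 and 0.13 ± 0.10. The list had a camera adjusted p of 0.0794. No member was called over all probe sets among the tested genes of brassinosteroids (3), of strigolactones and tillering (3), of class III peroxidases (3) or of the KNOX homeobox list (2). BRI1, the brassinosteroid receptor gene, had a log2 change of -0.33 ± 0.10, and D14, the strigolactone receptor gene, one of -0.12 ± 0.09. The KNOX gene OSH71, which is active in meristems, was at 48.2 ± 36.7 in wild type and 188.3 ± 50 in Epi-df, a log2 change of 1.78 ± 0.36 that missed the threshold over all probe sets (limma adjusted p = 0.0605). It was called over all probe sets without wild type replicate 3 (limma adjusted p = 0.0125). Without wild type replicate 1, wild type replicate 2 or Epi-df replicate 2 it was not (limma adjusted p = 0.223, 0.185 and 0.0620). Without Epi-df replicate 1 or 3 OSH71 was not among the tested probe sets. With all arrays, adjusted over the list alone, OSH71 was called among 2 genes (limma adjusted p = 0.00263) and no brassinosteroid, strigolactone or peroxidase gene was. The KNOX list leaves out OSH3 and OSH45, which the homeobox list holds. Their log2 changes were 0.33 ± 0.12 and -0.39 ± 0.09 (limma adjusted p = 0.251 and 0.0821 over all probe sets). Adjusted over the 39 tested homeobox genes, the limma adjusted p of OSH71 was 0.0312. Its intensities in wild type replicates 1 and 2 were 28.2 and 25.88, under the 80.54 at which the filter on the mean lay, so its fold rests on a low level.

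TIFY genes, most of them JAZ repressors of the jasmonate response, were lower in Epi-df in 14 of 15 tested members. JAZ1, TIFY1A and TIFY2B were lower by little, with log2 changes of -0.09 ± 0.07, -0.11 ± 0.10 and -0.05 ± 0.08. The groups did not overlap in 9 of the 15, among them TIFY2A, which was higher. The median log2 change of the list was -1.15. It was -0.64 without wild type replicate 1, -0.78 without Epi-df replicate 2 and -1.64 without wild type replicate 3. JAZ12 was the 1 called over all probe sets and fell by 1.84 ± 0.34 (limma adjusted p = 0.0455), and 6 members were called adjusted over the list alone. The list passed the camera test with a preset correlation (adjusted p = 4.36e-05), and did not with an estimated one (adjusted p = 0.595 with an estimated correlation). The arrays of a group differed strongly among themselves: the mean log2 level of the list was 11.63, 11.20 and 10.69 in the wild type arrays and 10.46, 9.80 and 9.86 in the Epi-df arrays. The call of JAZ12 was lost when wild type replicate 1 or 2 or Epi-df replicate 2 or 3 was left out, with adjusted p values of up to 0.177.

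**Figure D3:**
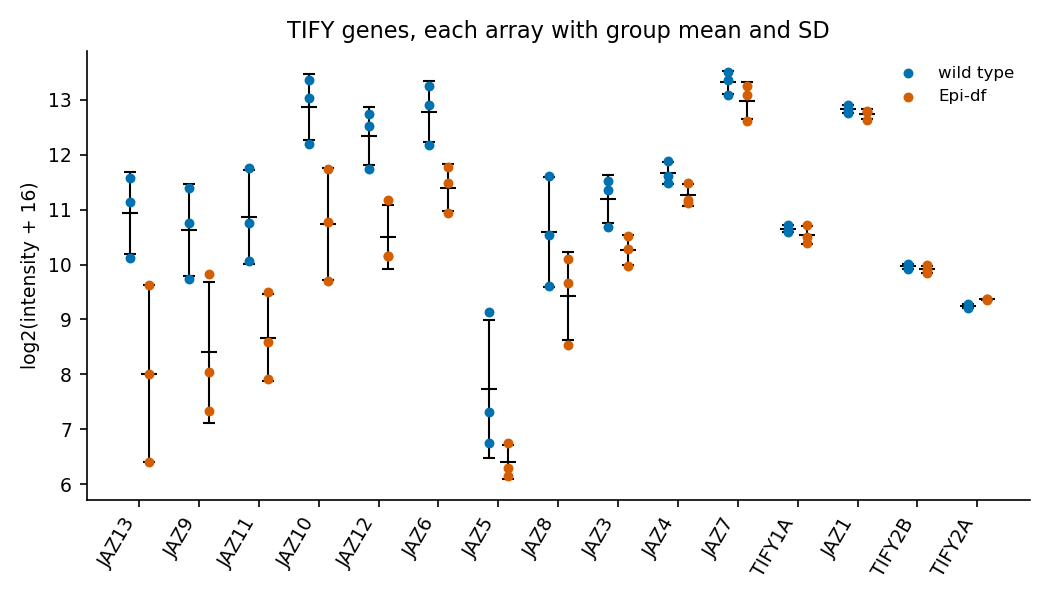
Log2(intensity + 16) of the 15 tested TIFY genes in each of 6 arrays, ordered by their log2 change. Points are single arrays and bars the mean and SD of 3 arrays, wild type blue and Epi-df orange. In 14 genes the Epi-df mean is the lower one, and the points of a group lie far apart in most JAZ genes.

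In the list of chitinase and pathogenesis-related genes, most of them chitinase genes, 11 of 13 tested members were higher. Their median log2 change over the list was 0.39 (camera adjusted p = 0.0313, and adjusted p = 0.626 with an estimated correlation). The dimmer of the chitinase genes named Cht1 was the 1 called and rose by 1.14 ± 0.12 from 65.4 ± 10.3 to 162.9 ± 22, and 5 members were called adjusted over the list alone, PBZ1 among them. PBZ1, a gene induced by probenazole and not a chitinase gene, went the other way. Its log2 change of -1.51 ± 0.36 did not pass over all probe sets (limma adjusted p = 0.0907). The list's adjusted p was 0.0784 without wild type replicate 3 and 0.164 without Epi-df replicate 3, where its median was 0.19, and its median was 0.66 without Epi-df replicate 2. Light harvesting and photosystem genes were higher in 7 of 8 tested members by small amounts, with a median log2 change of 0.23 and no member called over all probe sets or adjusted over the list alone (camera adjusted p = 0.0272, and adjusted p = 0.626 with an estimated correlation). The brighter of the chlorophyll-binding protein genes named LHCP had a log2 change of 0.28 ± 0.06. RBCS, the small subunit of Rubisco, had one of -0.02 ± 0.05. It stood at or near the highest intensity of every array (24975, the maximum, in wild type replicate 2), where a change may not show. The list's adjusted p was 0.0784 without wild type replicate 3 and 0.113 without Epi-df replicate 2, where its median was 0.14. None of the 3 tested root-expressed marker genes was called, and the silicon transporter gene LSI1 had a log2 change of 0.44 ± 0.14 (limma adjusted p = 0.184).

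Other named genes fell too. Adh2, an alcohol dehydrogenase gene, had a log2 change of -2.33 ± 0.42, PIN5A one of -2.07 ± 0.10 and a gene named ADPase one of -1.88 ± 0.18. For the sugar transporter gene SWEET14 it was -1.43 ± 0.12, for the cytochrome P450 gene CYP71Z6 -1.39 ± 0.13 and for the allantoinase gene ALN -1.22 ± 0.23. DREB1A, a transcription factor gene of the cold response, fell with a log2 change of -1.16 ± 0.19, and SAPK9, a protein kinase gene of the abscisic acid response, with one of -1.04 ± 0.12. Named genes that rose were the pectin methylesterase inhibitor gene PMEI8 by 2.02 ± 0.24, the bZIP gene TGAL11 by 1.63 ± 0.13, the glutathione transferase gene GSTU6 by 1.48 ± 0.23, the calmodulin-like gene CML31 by 1.42 ± 0.19, RBM8 by 1.23 ± 0.08 and the aquaporin gene PIP1-3 by 1.02 ± 0.16. The calls of PIN5A, ADPase, SWEET14, CYP71Z6, TGAL11, RBM8, MADS16, MADS50, MADS55 and the called Cht1 held without any single array. Those of Adh2, GSTU6 and PIP1-3 were lost in 4 of the 6 fits that each left out 1 array, those of ALN and DREB1A in 5 and those of PMEI8, CML31 and SAPK9 in 2. In these fits the log2 change of Adh2 lay between -2.73 and -1.87, with a highest adjusted p of 0.154, and the highest adjusted p was 0.191 for ALN, 0.139 for DREB1A, 0.125 for GSTU6 and 0.114 for PIP1-3. For PMEI8 and CML31 it was 0.0591 and 0.0626, and SAPK9 lost its call to the fold threshold, at a log2 change of -0.94.

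With all arrays and the settings of the main fit, the remaining lists did not pass the camera test. WRKY genes were lower in 6 of 6 members (median log2 change -0.67, camera adjusted p = 0.0783), with WRKY71 at -0.87 ± 0.29 (-0.57 without Epi-df replicate 2) and none called over all probe sets or adjusted over the list alone. Aquaporin genes were higher in 16 of 21 members (camera adjusted p = 0.0794), with PIP1-3 the 1 called over all and adjusted over the list alone. Sugar transporter and invertase genes (18 tested) and diterpenoid phytoalexin genes (7 tested) each had 1 call, SWEET14 and CYP71Z6, and dehydration and abscisic acid response genes (24 tested) had 2, DREB1A and SAPK9, with the same counts adjusted over the list alone (camera adjusted p = 0.177, 0.301 and 0.196). Auxin response genes (48 tested, camera adjusted p = 0.193) and homeobox genes (39 tested, 0.558) had no call over all probe sets and 1 each adjusted over the list alone, GH3.1 and OSH71. GH3.1 was called over all probe sets without wild type replicate 3 (limma adjusted p = 0.0468). In the other fits that left out 1 array it was not called, with limma adjusted p from 0.0930 to 0.285. Its intensities in wild type replicates 1 and 2, 45.8 and 49.23, lay under the filter level of 80.54, so its fold rests on a low level. No call was made, over all or over the list alone, among heat shock (20 tested, camera adjusted p = 0.177), nitrogen (17, 0.177), DNA replication (24, 0.177), cytokinin response regulator (12, 0.193), cellulose synthase (27, 0.196), ribosomal protein (25, 0.221) and cyclin genes (16, 0.247). The same held for expansin and xyloglucan (21, 0.301), histone (6, 0.492), phosphate starvation (15, 0.492), NAC (6, 0.768), anther and pollen (6, 0.790), iron and zinc transport (28, 0.827) and seed storage genes (10, 0.990). In the iron list, NAS2, Nramp1 and NAAT1 were high in Epi-df replicate 3 alone, and without this array 205 probe sets were called between the lines, 160 of them among the 209. Without it the cyclin and DNA replication lists passed, with median log2 changes of 0.29 and 0.27 against 0.11 and 0.17 with all arrays (camera adjusted p = 0.00367 and 0.00531). They did not pass when any other single array was left out. Without Epi-df replicate 1 their medians were 0.05 and 0.08 (camera adjusted p = 0.499 and 0.320), and without Epi-df replicate 2 they were -0.001 and 0.09 (camera adjusted p = 0.901 and 0.282). Leaving out wild type replicate 2 let the WRKY list pass (0.0224, median -0.93), wild type replicate 1 the aquaporin list (0.0306, median 0.09) and Epi-df replicate 2 the cytokinin list (0.0427, median -0.33). The lowest and highest medians in the fits that left out 1 array were -0.93 and -0.36 for the WRKY list, 0.04 and 0.10 for the aquaporin list and -0.33 and -0.04 for the cytokinin list, against -0.67, 0.05 and -0.13 with all arrays. The WRKY and cytokinin medians nearest 0 were those without Epi-df replicate 2 (camera adjusted p = 0.113) and without Epi-df replicate 3 (camera adjusted p = 0.477). With all arrays and an estimated correlation, the adjusted p was 0.790 for the cyclin, DNA replication and cytokinin lists and 0.595 for the WRKY and aquaporin lists. Below the fold threshold, NAC6, a stress-related transcription factor gene, had a log2 change of -0.79 ± 0.11 (limma adjusted p = 0.0188), and HSP18.8 one of -0.32 ± 0.06 (limma adjusted p = 0.0453). When 1 array was left out, the adjusted p of HSP18.8 lay between 0.0666 and 0.176, and that of NAC6 was 0.0612 without wild type replicate 2.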

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

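Apart from the fits named here, the count of 209 changed probe sets stayed within 1.5 times under each alternative. It was 617 with no fold threshold and 496 at 1.5-fold. It lay between 108 and 250 when 1 array was left out: 108 without wild type replicate 1 and 114 without wild type replicate 2, of which 100 and 106 were among the 209. With the replicate block it was 319. Deviations of same-numbered arrays correlated at 0.139, 0.336 and -0.0537 for numbers 1, 2 and 3, and 4 of 6 arrays correlated best with their own number. So few correlations do not settle whether the numbers pair the samples. The share of higher calls, 28.7% with all arrays, was 28.8% and 29.4% under the other scalings, 24.8% with the block and 32.1% with array weights. Leaving out 1 array it lay between 23.6% (without wild type replicate 3) and 41.2% (without Epi-df replicate 2, 89 higher and 127 lower). Of the gene lists, the TIFY list lost its call with an estimated correlation (adjusted p = 0.595) and fry (0.099), and kept it under the other alternatives. The photosystem list lost it with an estimated correlation (0.626), fry (0.190) and in 2 of the 6 fits that left out 1 array, which gave 0.00553 to 0.113. The chitinase list lost it with an estimated correlation (0.626), fry (0.239), the 60th percentile filter (0.0730), without _s_at and _x_at probe sets (0.0692), and in 2 of the 6 fits that left out 1 array, which gave 0.00465 to 0.164. The other 24 lists passed in 9 of 454 values, over 7 lists, with the WRKY list at 0.0152 with the block. Of 22 called named probe sets, 11 kept the call in every fit that tested them. Leaving out 1 array, a peroxidase gene lay between -0.25 (without Epi-df replicate 3) and 1.115 on the log2 scale, against 0.44, and YSL16 between -0.18 and 0.086 (without Epi-df replicate 2), against -0.09, and neither was called. The causes were not tested. With no filter 250 probe sets were called, 72 higher and 178 lower, with all of the 209 among them.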

Other observations

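Some genes of the iron deficiency response stood apart in 1 array. NAS1 and NAS2, for nicotianamine synthases, were at 10.08 and 9.46 on the log2(intensity + 16) scale in Epi-df replicate 3, and at no more than 6.02 and 6.38 in the other 5 arrays. NAAT1, a gene of phytosiderophore synthesis, was at 10.48 against at most 8.12, the metal transporter gene Nramp1 at 11.40 against at most 8.48, and the iron transporter gene IRT2 at 7.88 against at most 6.26. IRT1 and YSL15 were close to the other arrays, at 6.61 and 7.09 against at most 6.59 and 7.15. Other genes of the iron list went the other way. NAS3, also a nicotianamine synthase gene, was lowest in Epi-df replicate 3, at 9.48 against at least 9.99. NRAMP5, YSL6 and YSL9 were among others lowest there, at 9.16, 10.50 and 7.33 against at least 9.49, 10.825 and 7.845. In the same array 3 of the 4 tested CYCB mitotic cyclin genes were at their lowest, CYCB1-1 at 9.07 against at least 9.70 in the others. These genes were singled out after their values were seen, and without this array 205 probe sets were called between the lines, 160 of them among the 209, and the cyclin and DNA replication lists passed as higher in Epi-df (camera adjusted p = 0.00367 and 0.00531, against 0.247 and 0.177 with all arrays, and adjusted p = 0.790 for both with all arrays and an estimated correlation). Without Epi-df replicate 2 instead, the median log2 changes of these lists were -0.001 and 0.09 (camera adjusted p = 0.901 and 0.282), against 0.11 and 0.17 with all arrays.

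The test of sample-to-sample spread in the TIFY genes was chosen only after the result was seen, and so were the fits of the synthesis genes that left out 1 array. The synthesis genes were listed after the TIFY result but before their own values were seen. The TIFY genes were lower in Epi-df in 14 of 15 tested members. The 7 jasmonate synthesis genes tested, AOS1, AOS2, AOC, OPR7, LOX8, LOX9 and JAR1, had a median log2 change of -0.53, just past the bound of -0.5 set beforehand, and none was called with all arrays. Without wild type replicate 1 the median was -0.42, short of that bound, and in the other fits that left out 1 array it lay between -0.73 and -0.54. AOS1 had a log2 change of -0.91 ± 0.29 and LOX8 one of -0.12 ± 0.67. AOS1 was called without wild type replicate 3, at -1.24 (limma adjusted p = 0.0464). LOX8 was higher in Epi-df replicates 1 and 3, at 10.68 and 11.36, than in any wild type array, at most 10.39, and was at 8.36 in Epi-df replicate 2. Without that array its log2 change was 0.77. The spread of the TIFY genes within groups, above that of 100% of random lists matched on level, was tested on the genes in which it had been seen, so this test decides nothing. AOC and AOS1 also fell within the wild type, from 12.38 and 11.59 in replicate 1 to 11.445 and 10.57 in replicate 3. The TIFY mean fell there too, while AOS2, LOX8 and LOX9 were lowest in wild type replicate 2. Passing the bound of -0.5 therefore does not tell the explanations apart, and jasmonate itself was not measured. Lower jasmonate synthesis in Epi-df and a jasmonate response that varied from seedling sample to sample may each lie behind the TIFY values, and both stay open.

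Called genes lay side by side on the chromosomes more often than random draws. Of 131 called genes, 7 pairs of neighbouring tested genes were called in 1 direction, against 0.633 on average in 10000 draws matched on level, and above 100% of them. Without the _s_at and _x_at probe sets, which can bind several transcripts, there were 6 pairs, again above 100% of draws, which argues against these shared probe sets as the source. The only pair that rose was MADS27 and LOC4329768, by 1.15 and 1.73 on the log2 scale. All the others fell, among them LOC9267533 and LOC4350599 with log2 changes of -1.39 and -4.69. Duplicated neighbours that share a regulator, a stretch of chromatin that changed as a unit and probe sets that cross-hybridise without such a suffix may each give such pairs, and the data used here do not tell them apart.

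The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 209 calls and the highest of the other splits gave 0, so that 1 split, the real one, gave as many as 209. Each of the other splits mixes the lines, so that a difference between the lines adds to the spread within its groups. Few calls were therefore likely there beforehand, and the 0 is not a rate of false calls.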
